A study of Drosophila melanogaster with 63 samples.

How the data were processed

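RNA of treated and control flies or larvae was hybridised to spotted arrays with 2 dye channels, and 63 arrays were used here. Per the labels, each array was scanned 3 times at different intensities, and both spot copies of a clone and all repeat hybridisations were merged into 1 value, which is therefore repeated on every array of a group. The deposited values fit this: all arrays of each of the 12 groups held the same column, and both spots of each of 12094 clones held the same value (24188 of 32448 spot identifiers had values). The normalisation behind the merged value, the background correction and the choice between scans are not given in the sources used here. The intensities, flags and single-array ratios of the scanner were not used here. The labels of 1 array at 100 h also speak of a confidence filter, which the values do not show, since 12071 of 12094 clones had a value at that age.

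The authors' deposited values are log2 ratios. Their base was settled from the values: 2 raised to their size is a number of 6 decimals, within 0.05 of the last decimal, in 99.996% of 289992 values, against 9.98% for base e and 9.87% for base 10, about what chance gives. Medians over clones were -0.03 to 0.02 in the columns, and the values thus look centred near 0, but how they were centred is unknown. The direction is not stated for the ratios and is called likely treated over control in the report, with its basis.

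Clones were named through the platform annotation, with symbols updated by gene identifier and then by transcript accession to the RefSeq annotation of the assembly Release 6 plus ISO1 MT. Of the 12094 clones 9814 were named by gene identifier, 87 by accession and 247 by the annotation's symbol alone. A further 1945 had no gene symbol and 1 had several, and these were left unnamed. Thus 10148 clones had 1 symbol. The symbol nan, of the gene nanchung, was read as a name and not as a missing value. A gene is the median over its clones, which gave 9212 genes, 773 of them with more than 1 clone and 9158 with a value in all 12 groups. No filter on low values was made, since the values used are ratios, and the brightness of a spot, which sets the precision of its ratio, was not used here. The number of arrays, 4 to 6 per group, limits the precision.

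Genes were counted where the ratio was at least 2-fold from the control. A test was planned for the case that single arrays carried their own values. As they did not, the branch fixed for values without a test applied, no model was fitted, no p-value is given, and the words higher and lower describe values. Differences between groups are the first ratio minus the second, for 3 comparisons of females with males, 3 of starvation with sugar and 3 of 48 h with 24 h. Correlations and covariances are across genes. The number of shared genes expected for independent lists is the product of both counts over the number of genes measured in both. A simulation of shared controls needs the spread between arrays and could not be made. A larval trend was counted where the ratio was higher, or lower, at each of the 4 steps from 52 to 100 h and at least 2-fold from the control at 100 h.

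The 28 gene lists, the comparisons, the threshold and the rule for named genes were fixed before the data were examined. The rule takes the 8 highest and 8 lowest genes of each group, of which CG-numbered genes after the first 3 per direction are left out of the text, the 2 highest and 2 lowest members of each list, the 6 largest differences in each direction, and the genes of the direction check. The text leaves out some genes that the rule would allow and marks those chosen after their values were seen. Lists cover metabolism (lipid breakdown, fatty acid synthesis, gluconeogenesis with glycogen and trehalose, glycolysis, purine and folate, amino acid breakdown, insulin and TOR), tissues (yolk and eggshell, germline, accessory gland and testis, digestive enzymes, muscle, eye, nervous system, blood cells, salivary gland, cuticle, larval serum proteins) and general functions (ribosomal proteins, nucleolus, proteasome, respiratory chain, DNA replication, immune genes, detoxification, heat shock, autophagy, ecdysone). The respiratory chain and proteasome lists were matched mainly by symbol pattern. They therefore also hold related genes such as COX4L, ND-51L1, Prosalpha3T and Rpt3R, which were not set apart. For lists with at least 4 measured genes, the median was set against 10000 random lists of the same size. Matching on expression level was not made, since the values used are ratios only.

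The counting and list steps were tested on simulated data for 9212 genes with normal noise set from the median difference between clones. That median was 0.12 in starved females at 24 h and 0.30 in larvae of 100 h. Real clone differences had heavier tails, with 95th percentiles of 0.53 and 1.08, so the shares of unmoved genes below are likely too low. For starved females at 24 h, 100% of genes moved by 1.5 on the log2 scale and 100% of those moved by 3 were counted, and 0% of genes not moved. For larvae of 100 h these shares were 96%, 100% and 0.144%. Of 40 simulated lists of 15 unmoved genes, 7.5% lay outside the middle 95% of random lists in either setting, and all 20 lists moved by 0.4 lay above it. Simulated genes were drawn independently, while genes of a real list are not independent. Their noise was also narrower than the SD over real genes, which was 0.30 in starved females at 24 h and 0.80 in larvae of 100 h. The list figures therefore do not carry over to the real lists. Alternatives covered the centring of columns, thresholds of 1.5-fold and 3-fold, clones counted singly, the first clone of a gene, genes complete in all groups, the list mean, trimmed lists and matching by file name. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.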

Results

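Gene expression was measured in Drosophila melanogaster of the OregonR wild-type strain on spotted arrays that compare a treated and a control RNA in 2 dye channels. The 63 arrays formed 12 groups, and the labels give a temperature of 25 C for all of them. In 38 arrays, adult flies kept without food on buffer (starved) or on buffer with 20% sucrose (sugar) were compared with adults of the same sex kept on yeast paste. In the other 25, larvae of 52, 64, 76, 88 or 100 h after egg laying were compared with larvae of 40 h. Starved females had 6 arrays at 24 h and 5 at 48 h, and starved males had 6 at 24 h. The 63 arrays carry 62 array numbers, since 2 of the 5 of females starved for 48 h have the same number with opposite dye orientations, and whether these are separate arrays is not given. On sugar, females had 5 arrays at 24 h and 6 at 48 h, and males had 6 and 4. The larval ages had 6, 5, 6, 4 and 4 arrays, from the youngest to the oldest. Both dye orientations were present in every group. The series title names the question, how flies respond to starvation and what this means for metabolism that differs between the sexes and for aging.

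All arrays of a group carried identical merged values, so each group was 1 measurement per gene, with no spread between replicates and no test. Values are log2 ratios, a gene is the median over its clones, and 9212 genes were measured. For each of the 645 genes with exactly 2 clones, the difference between the clones gives a technical yardstick. Its 95th percentile was 0.36 in starved males, 0.37 and 0.50 in males on sugar at 24 and 48 h, 0.53 and 0.74 in starved females, and 0.50 and 0.78 in females on sugar. In larvae it was 0.62, 0.65, 0.85, 0.91 and 1.08 from 52 to 100 h. It holds nothing of the variation between animals. A gene list is said to stand above or below random lists where its median lay outside the middle 95% of 10000 random lists of the same size.

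The sign of the ratio is likely treated over control. The labels name the control of each array, and Lsp2, a storage protein that the fat body of late larvae makes in large amounts, was at 8.52 at 88 h and 8.26 at 100 h. It was the only measured gene of the 5 fixed for the larval check. In starved adults, the median of Lip3 and Lip4, lipases known from fasting, and Pepck1, an enzyme of gluconeogenesis, was 0.04 in females at 24 h, 0.78 in females at 48 h and -0.02 in males. Both the females at 24 h and the males thus lay near 0, well inside the spread between clones, and only females at 48 h had the higher values looked for. Lip3 lay at -0.05, 0.18 and -0.33 in those 3 groups, at -0.14 and -0.51 in females on sugar, and at -0.50 and -0.97 in males on sugar. Lip4 lay at 0.13, 0.89 and -0.02 in the starved groups and at -0.30, 0.09, -0.54 and -0.77 in the sugar groups in the same order. In larvae, Lip3 was at 0.41, 0.89, 1.39, 1.87 and 2.41 from 52 to 100 h, and Lip4 was at -0.17, 0.19, 0.13, 0.50 and 0.29. Pepck1 was at 0.38, 0.02, 2.00, 2.49 and 2.12 at those ages. Without a sign, the number of genes at least 2-fold from the control was 108 and 181 in starved females, 54 in starved males, 139 and 273 in females on sugar, and 114 and 188 in males on sugar. It was 210, 109, 450, 687 and 1080 in larvae from 52 to 100 h.

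**Figure D1:**
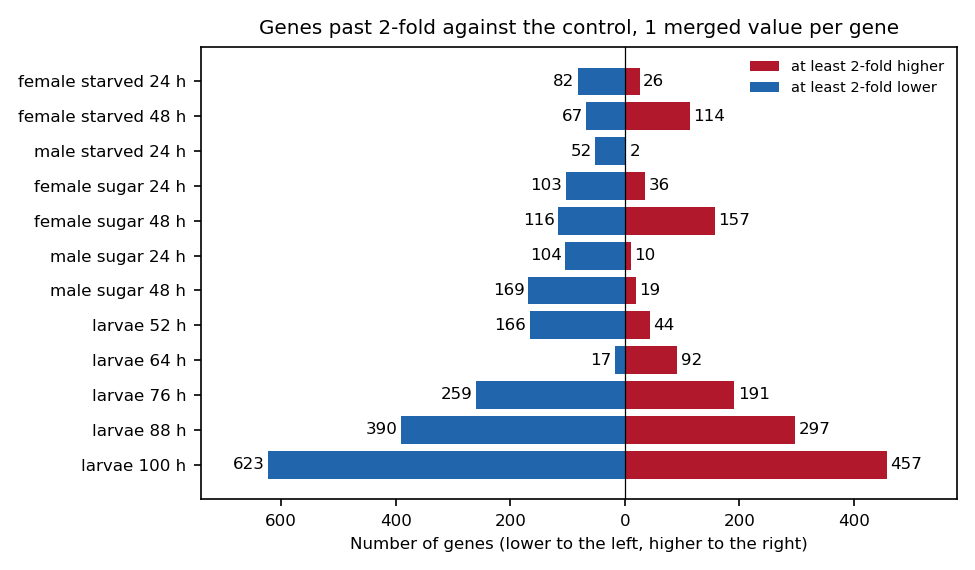
Bars show the number of genes at least 2-fold higher (red, right) or lower (blue, left) than the control in each of the 12 groups, with 1 merged value per gene and no error bars. Larvae of 100 h had the most in both directions, with 457 higher and 623 lower.

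In starved females, genes of the eggshell and yolk were far below the yeast-fed control. At 24 h, 13 of the 15 members of the yolk and eggshell list were at least 2-fold lower, with a list median of -2.19, and at 48 h all 15 were, with a median of -2.43. The vitelline membrane genes Vm32E (-3.30) and Vm34Ca (-2.72) and the chorion genes Cp19 (-2.57) and dec (-2.50) were among the 8 lowest genes at 24 h. Cp38 (-4.30), Cp19 (-4.25), Cp36 (-3.99), Cp16 (-3.62) and fit (-3.63) were among them at 48 h. The yolk protein genes stood nearest the control in the list, with Yp1 at -0.64 and Yp3 at -0.97 at 24 h. Lsp2 was lower still, at -5.63 and -7.25. CG11538 lay beside it at -5.91 and -8.09. Its name is an older one of both Lsp2 and an antisense RNA that overlaps Lsp2, and with no strand recorded the pair is uncertain as separate genes.

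The muscle, eye and nervous system lists stood above random lists in starved females, though at 24 h only 2 eye genes and no gene of the other lists were at least 2-fold higher. The muscle list (12 genes, among them sls and bt, which encode giant sarcomere proteins) had a median of 0.40 at 24 h and 0.88 at 48 h, when sls was at 1.32 and bt at 1.22. The eye list had medians of 0.53 and 0.99 over 10 genes. Arr2, an arrestin of photoreceptors, was at 1.61 and 1.78, and 5 of the 10 genes were at least 2-fold higher at 48 h. The nervous system list was at 0.18 and 0.68, with futsch at 0.71 and Appl at 0.51 at 24 h. The highest single genes at 24 h were CG1648 (2.35), nes (2.18), an acyltransferase gene, Cyp4g1 (2.18), a cytochrome P450 of hydrocarbon synthesis, and Non1 (1.90). At 48 h they were Cyp4e3 (2.42), CG1648 (2.11), Apoltp (1.95), MtnA, a metallothionein (1.94), CG8654 (1.92), and DptB, an antimicrobial peptide (1.86). The insulin and TOR list stood above random lists at 0.29 and 0.43, with the kinase Lk6 at 0.84 and 0.88 and the insulin receptor InR at 0.68 at 24 h.

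The proteasome list (35 genes) was at -0.30 and -0.34 in starved females without any member past 2-fold. Purine and folate metabolism was at -0.20 (4 of 21 genes at least 2-fold lower) and -0.21 (2 of 22). That list was written with the topic of the study in mind, so its direction here and in the other groups is not independent evidence. At 24 h CG11089 was at -1.75, between clones of -2.23 and -1.26, and Shmt at -1.55, and at 48 h pug was at -1.18 and Prat2 at -1.17. The list of DNA replication and cell cycle genes stood below random lists at 48 h (-0.34), with Prim2 at -0.60 and PCNA at -0.57. Immune genes stood above random lists at 48 h (0.44), with 3 of 15 at least 2-fold higher, among them DptB and Drs (1.22). In all, 26 genes were at least 2-fold higher and 82 lower at 24 h, and 114 and 67 at 48 h. At 3-fold the balance at 48 h was turned, with 14 higher and 36 lower.

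In starved males, digestive enzyme genes were below the yeast-fed control. Of the 39 digestive enzyme genes, 9 were at least 2-fold lower and none higher, with a list median of -0.57. The serine proteases Jon25Bi (-2.61) and Jon66Ci (-1.89) were the lowest of them. Lsp2 was at -5.46. Metabolic lists were also below random lists: amino acid breakdown at -0.52 with Oat, ornithine aminotransferase, at -1.47, purine and folate metabolism at -0.45 with Shmt at -1.29 and CG3999 at -1.15, and gluconeogenesis, glycogen and trehalose at -0.35 with AGBE, the glycogen branching enzyme, at -1.34 and Glys, glycogen synthase, at -1.06. Fatty acid synthesis was at -0.28 with ATPCL at -0.95. PGRP-SC2, a peptidoglycan recognition protein of the gut, was at -1.19, in an immune list with a median of -0.25. The detoxification list of 124 genes was at -0.12 with GstE9 at -1.08.

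Only 2 genes were at least 2-fold higher in starved males, CG13558 (3.27) and Non1 (1.09), against 52 lower. The next highest were CG3631 (0.91), CG3280 (0.87), Apoltp (0.81), Klp67A (0.74), Pp2B-14D (0.74) and Nap1 (0.70). The insulin and TOR list stood above random lists at 0.21, with InR at 0.51, and the eye list at 0.14, while the muscle list lay at -0.03 and the nervous system list at 0.04. The other low genes were CG15879 (-3.36), pwn (-2.64), CG11247 (-2.34) and DnaJ-H (-2.20). The 2 clones of CG11247 disagreed, at -4.68 and -0.01.

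In females on sugar the eggshell genes were also far below the control. Of the 15 yolk and eggshell genes, 14 were at least 2-fold lower at 24 h and all 15 at 48 h, with medians of -2.64 and -2.76. Vm32E was at -3.42 and -3.77, Cp19 at -3.34 and -3.66, and yellow-g, an eggshell gene, at -3.07 at 24 h. Lsp2 was at -6.04 and -6.71. Muscle (0.49 and 0.91), eye (0.54 and 0.95) and nervous system (0.19 and 0.48) lists were again above random lists, with Arr2 at 1.44 and 2.15, sls at 1.51 and bt at 1.46 at 48 h. The 2 clones of bt then lay at 0.83 and 2.09.

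Among the highest genes on sugar in females were CG7798 (2.74), CG1648 (2.54), Cyp4g1 (2.05), CG4716 (2.03), Non1 (1.65) and Sgp (1.45) at 24 h. At 48 h CG5773 (2.90), CG1648 (2.26), CG7720 (2.24), Cyp4g1 (2.19) and FASN2, a fatty acid synthase (2.06), were among them. The insulin and TOR list had medians of 0.49 and 0.50, with sug, a zinc finger transcription factor of sugar sensing, at 0.92 and 1.64 and Lk6 at 0.95 and 0.99. Purine and folate metabolism was at -0.55 and -0.42 over 22 genes, with 7 and 4 at least 2-fold lower, Gnmt, glycine N-methyltransferase, at -2.41 at 24 h and pug at -1.71 at 48 h. Digestive enzymes were at -0.31 and -0.34, but in both directions: 10 and 9 of 39 were at least 2-fold lower, as Jon25Bi (-2.29 and -2.41) and Jon99Ci (-1.99 and -2.29) were, and 2 and 6 were at least 2-fold higher, as epsilonTry (1.09 and 1.33) was. Tps1, which makes trehalose, was at 0.93 and 1.08, while AGBE was at -1.58 and -0.56. The proteasome list was at -0.36 and -0.26, and immune genes were at -0.31 at 24 h with PGRP-SC2 at -1.52. Sugar-fed females had 36 genes at least 2-fold higher and 103 lower at 24 h, and 157 and 116 at 48 h. At 3-fold the balance at 48 h was turned, with 29 higher and 53 lower.

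In males on sugar, enzymes of purine, folate and amino acid metabolism were lower than on yeast. Of the 22 purine and folate genes, 12 were at least 2-fold lower at 24 h and 14 at 48 h, with medians of -1.06 and -1.59 and none higher, in the list chosen with the study's topic in mind. CG11089, a gene of purine synthesis, was at -2.85 and -3.27, Gart, which carries 3 activities of the same pathway, at -2.26 and -3.28, and Shmt, serine hydroxymethyltransferase, at -2.22 at 24 h. The clones of CG11089 ranged from -3.35 to -2.34 at 24 h. Amino acid breakdown was at -0.93 and -1.26, with Oat at -1.68 and -2.92 and Hpd, an enzyme of tyrosine breakdown, at -1.85 and -1.91. Gluconeogenesis, glycogen and trehalose genes were at -1.11 and -1.25, with 5 and 7 of 10 at least 2-fold lower. Pepck1 was at -1.73 and -1.49, against -0.87 and -0.25 in females on sugar. It was at 0.04 and 0.78 in starved females and 0.21 in starved males.

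Digestive enzymes had medians of -0.45 at 24 h and -1.11 at 48 h in males on sugar, and 14 and 20 of the 39 were at least 2-fold lower. Jon25Bi was at -1.99 and -3.88, Jon25Bii at -3.31 and LManVI, a lysosomal mannosidase gene, at -3.43 at 48 h. Fatty acid and triglyceride synthesis was at -0.28 and -0.56, with ATPCL, ATP citrate lyase, at -1.22 and -1.66 but FASN2 at 0.71 and 0.89. Glycolysis was at -0.28 and -0.47 with Pgi at -1.28 and -1.23, and lipid breakdown at -0.29 and -0.18 with bmm, a triglyceride lipase, at -1.13 and -1.38. PGRP-SC2 (-1.43 and -2.29) and PGRP-SC1a (-1.36 and -1.77) were the lowest immune genes. Yolk and eggshell genes were at -0.02 and 0.18, and muscle genes at -0.04 and -0.07. The highest genes at 24 h were, among others, CG13558 (4.95), CG5773 (2.02), Atg12 (1.14) and cbt, a transcription factor (1.08). At 48 h wap (1.82), CG4998 (1.80), CG5773 (1.79), CG7720 (1.73) and mTTF (1.57) were highest, and sug was at 1.05 at 24 h. Sugar-fed males had 10 genes at least 2-fold higher and 104 lower at 24 h, and 19 and 169 at 48 h.

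**Figure D2:**
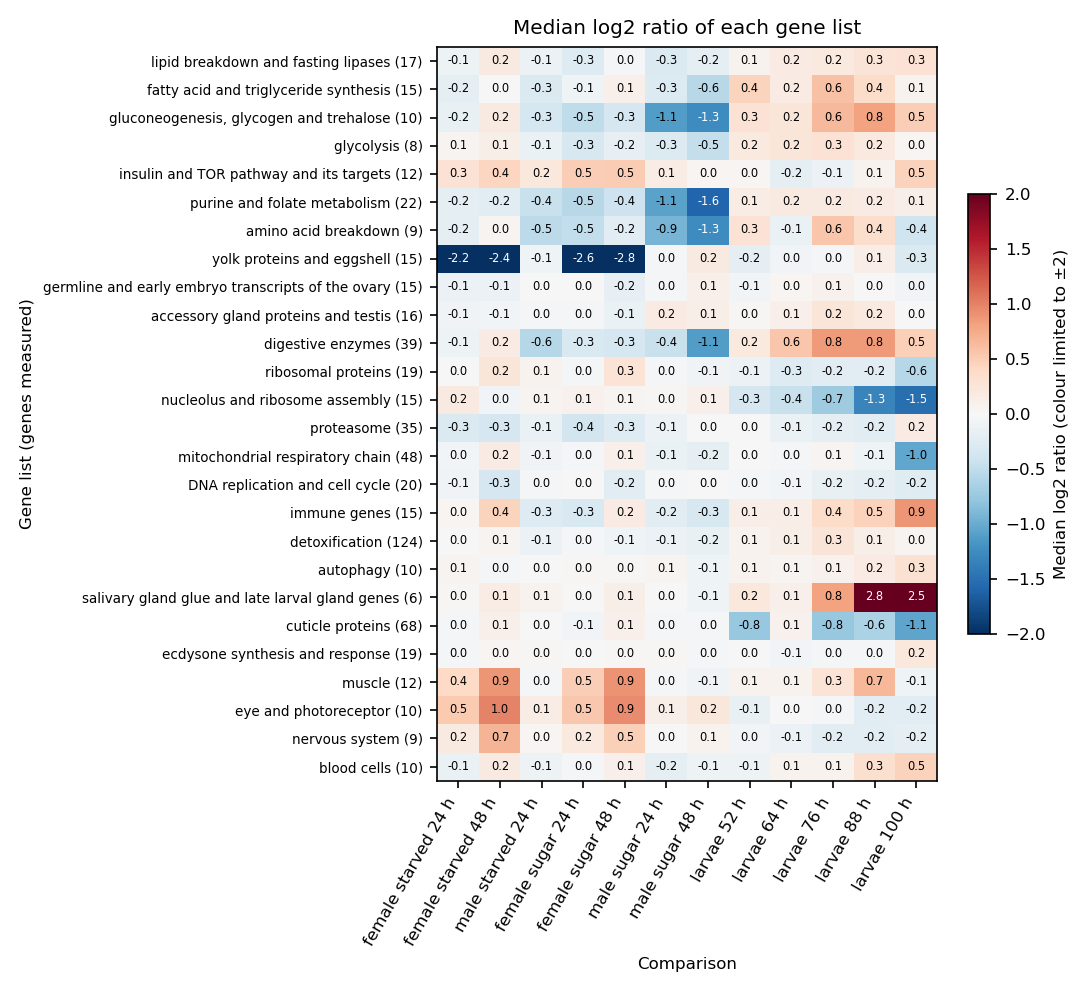
Each cell gives the median log2 ratio of a gene list (rows, with the number of genes measured) in each of the 12 groups (columns), rounded to 1 decimal; red is higher and blue lower than the control, with colours limited to ±2. The yolk and eggshell list reached -2.76 in females on sugar, and the purine and folate list -1.59 in males on sugar.

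The ratios to yeast-fed controls of the same sex differed between females and males in eggshell, muscle and digestive genes on both diets. Spot brightness was not used, so male ratios of eggshell genes near 0 do not tell steady expression from none. After 24 h of starvation the female ratio minus the male ratio was at least 2-fold apart in 90 genes, 39 with females above and 51 with females below. The difference was 3.95 for CG15879, 3.57 for nes, 2.38 for Cyp4g1 and 1.81 for Sgp, and -3.23 for Vm32E, -2.75 for Vm34Ca and -2.44 for Cp19. CG15879 rests on 1 clone and passed 2-fold in starved males alone among the adult groups. Digestive enzymes differed by a median of 0.46, with females above in 35 of 38, and muscle genes by 0.51. On sugar, 89 genes were at least 2-fold apart at 24 h (29 with females above) and 336 at 48 h (237 with females above). These balances depend on the threshold: at 3-fold 31 genes were above and 44 below in females at 48 h of sugar, and at 1.5-fold 216 were above and 147 below in starvation and 211 and 156 at 24 h of sugar. At 24 h Cyp4g1 (1.84), Obp99b (1.60) and Gart (1.52) were furthest above in females, and CG13558 (-3.94), Vm32E (-3.44) and Cp19 (-3.17) furthest below. At 48 h they were Gart (2.59), Oat (2.32) and Drs, an antifungal peptide gene (2.14), and Vm32E (-3.78), Cp19 (-3.78) and Cp16 (-3.59).

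The purine and folate list differed between the sexes by a median of -0.04 in starvation, 0.52 at 24 h of sugar and 1.10 at 48 h, when 12 of 22 genes were at least 2-fold above in females. At 24 h of sugar the digestive list differed by 0.23 and the muscle list by 0.52. At 48 h of sugar the digestive list differed by 1.00, with females above in all 39 genes, and the muscle list by 1.01. Gluconeogenesis, glycogen and trehalose then differed by 0.90, amino acid breakdown by 0.85, and fatty acid synthesis by 0.82. Whether an offset shared with muscle genes lies behind these differences at 48 h was looked at for the purine and folate list alone, in the closing part. It could not be decided there, since the limits used are spreads over genes. FASN1, a fatty acid synthase, was at 1.00 in females and -0.74 in males at that time. The ratio of the proteasome list to yeast was lower in females than in males, by -0.24, -0.25 and -0.26 in the 3 comparisons. Across genes, which are not independent replicates, r between the sexes was 0.39 in starvation and 0.50 and 0.28 on sugar at 24 and 48 h, with covariances of 0.0255, 0.0417 and 0.0417. Genes at least 2-fold lower in both sexes numbered 21, 45 and 44, where independent lists would share 0.438, 1.16 and 2.11. Those higher in both numbered 1, 6 and 10, against 0.00283, 0.038 and 0.324.

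**Figure D3:**
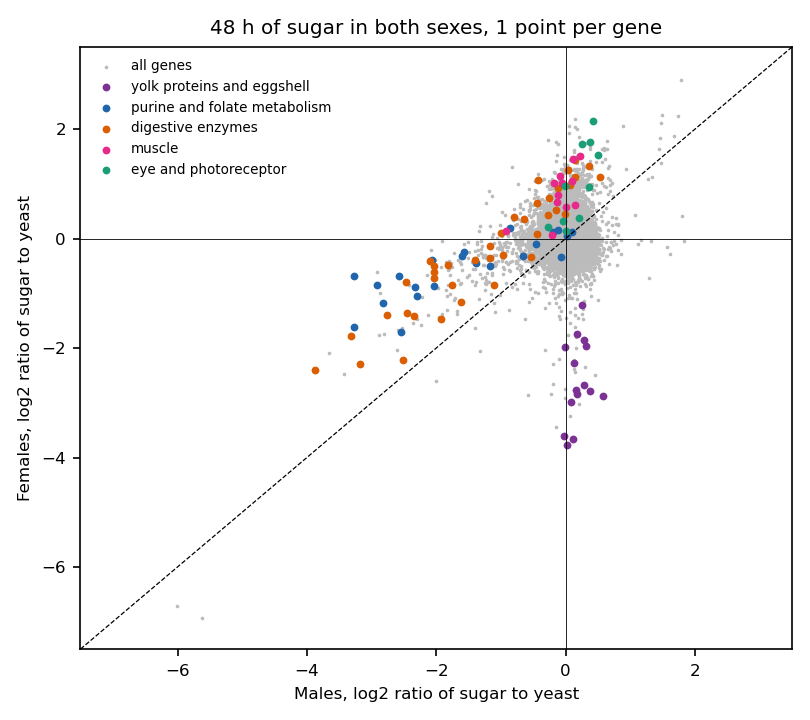
Each point is a gene, with its log2 ratio after 48 h of sugar in males (x axis) and in females (y axis); colours mark 5 gene lists, and the dashed line marks equal ratios. Digestive enzyme genes lay above the line in all 39 cases, and eggshell genes lay near 0 in males with a median of 0.18 and far below it in females with -2.76. The ratios near 0 in males do not tell steady expression from none.

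Starved and sugar-fed females resembled each other closely at 24 h, with only 11 genes at least 2-fold apart. Starvation lay above sugar for nes (1.52), PGRP-SC1a (1.22), TwdlD (1.21) and naz (1.02), and below it for CG7798 (-2.47), CG13138 (-1.25), CG5773 (-1.05) and FASN1 (-0.95). At 48 h, 86 genes were apart, 73 with starvation above. DptB (2.06), LManVI (2.03), Cyp4e3 (2.00) and CG14668 (2.99) led them, and Cp38 (-1.51), CG15056 (-1.69) and HPS4 (-1.25) were among the furthest below. Cyp4e3 and CG14668 rest on 1 clone each, and each passed 2-fold in a single adult group. Digestive enzymes were higher in starvation than on sugar by a median of 0.31 at 48 h (32 of 39), and purine and folate genes by 0.23. In males at 24 h, 52 genes were apart, 18 with starvation above and 34 below, but at 1.5-fold 87 were above and 71 below. CG11089 (1.95), Pepck1 (1.94), Miox, an enzyme of inositol breakdown (1.43), Sardh (1.40) and Gart (1.37) were higher in starvation, and pwn (-2.44), DnaJ-H (-2.44) and CG15879 (-3.14) lower. The genes pwn, DnaJ-H and CG15879 rest on 1 clone each and passed 2-fold in no other adult group than starved males. The purine and folate list was 0.56 higher in starved than in sugar-fed males, with 18 of 21 genes above 0, and the digestive enzyme list differed by -0.21.

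Across genes, r between starvation and sugar was 0.87 and 0.78 in females at 24 and 48 h and 0.67 in males at 24 h, with covariances of 0.0869, 0.133 and 0.0378. Genes at least 2-fold lower under both diets numbered 71, 59 and 32, against 0.911, 0.844 and 0.583 for independent lists, and those higher under both numbered 20, 79 and 1, against 0.0991, 1.94 and 0.00218. Whether the diets shared control RNA is not given in the sources used here, so part of this excess may come from shared controls.

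From 24 to 48 h of starvation, female ratios were at least 2-fold higher in 58 genes and lower in 21, but at 3-fold higher in 4 and lower in 7. Cyp4e3 (2.17), DptB (1.68), CG5966 (1.74), Tom7 (1.56) and the neuropeptide gene Nplp3 (1.53) were furthest above, and Cp38 (-1.96), Cp36 (-1.71), Cp19 (-1.68), Lsp2 (-1.62) and nes (-1.61) furthest below. Immune genes were higher at 48 h by a median of 0.56, lipid breakdown by 0.40 and gluconeogenesis, glycogen and trehalose by 0.43. In females on sugar 38 genes were higher and 25 lower at 48 h, among them TwdlM (1.95), Gnmt (1.90) and Vajk3 (1.86), and Jon25Bii (-1.80) and Amy-p, an amylase (-1.53). Muscle and eye lists were higher by 0.44 and 0.47. In males on sugar 16 were higher and 31 lower, with wap (1.74), Dap160 (1.54) and mTTF (1.52), and Jon25Bii (-3.48), Atg12 (-2.45), LManV (-1.90) and Jon25Bi (-1.88). Digestive enzymes were lower by a median of -0.51 and purine and folate genes by -0.38. Across genes, r between the times was 0.64 in starved females, 0.75 in females on sugar and 0.78 in males on sugar, with covariances of 0.0772, 0.107 and 0.0669. Genes lower at both times numbered 47, 77 and 95, against 0.598, 1.30 and 1.91 for independent lists, and those higher at both numbered 20, 29 and 6, against 0.323, 0.614 and 0.0186. In starved females no array lot was common to both times, and the sugar groups shared only part of their lots, so with merged values lot and time cannot be separated here.

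In larvae of 52 h many cuticle genes were lower than at 40 h, and Lsp2 and Fbp2 were among the highest genes. Of 68 cuticle genes 31 were at least 2-fold lower, with a list median of -0.75, among them TwdlD (-3.73), Cpr65Ea (-3.18), TwdlW (-3.16) and TwdlG (-3.13). Muc91C (-3.75), a mucin gene, and Osi2 (-3.06) were also among the 8 lowest. Lsp2 was at 3.28, Fbp2, a fat body protein gene, at 2.91, CG42500 at 2.18, Jig at 1.95 and Obp99b at 1.86, between clones of 1.39 and 2.33. Fatty acid synthesis was at 0.45 with FASN1 at 1.01, and the nucleolus list at -0.34 with mod at -0.68. At this age 44 genes were at least 2-fold higher and 166 lower.

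At 64 h the cuticle genes were close to their 40 h level, with a list median of 0.08 and 5 of 68 at least 2-fold higher and 2 lower. TwdlJ was at 2.57 and Cpr67Fa1 at 1.28, while TwdlC (-1.77) and TwdlD (-1.56) were lower. At this age 17 genes were at least 2-fold lower, against 92 higher, but at 1.5-fold the split was less uneven, with 225 lower and 339 higher. CG4362 (3.01, clones at 2.57 and 3.45), CG6277 (2.56), CG42807 (2.49) and Acbp6, an acyl-CoA binding protein gene (2.19), were among the highest, and Clk, a transcription factor of the circadian clock, was at -1.81 and LanA, a laminin gene, at -1.25. Digestive enzymes had a median of 0.56, with Amy-p at 1.49 and Jon99Ci at 1.23. Lsp2 was at 2.15 and Fbp2 at 2.04.

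At 76 and 88 h Lsp2 and Fbp2, both known from the fat body, were among the highest genes. Lsp2 was at 6.09 and 8.52, Fbp2 at 6.27 and 7.85, CG42500 at 5.03 and 6.63, and Obp99b at 4.09 and 5.55, although the clones of Obp99b ranged from 3.26 to 4.92 and from 4.34 to 6.76. The lipase gene mag was at 3.19 and 4.48, Pepck1 at 2.00 and 2.49, and FASN1 at 1.22 and 1.46. Digestive enzymes were at 0.85 and 0.84, with 12 and 18 of 39 at least 2-fold higher and Amy-p at 2.15 and 2.93. The salivary gland list of 6 genes was at 0.81 and 2.78, with ng2 at 2.34 and 3.14 and Eig71Ee at 3.30 at 88 h. Cuticle genes were again lower, at -0.75 and -0.63, with TwdlD at -4.74 and -5.60 and TwdlF at -4.21 and -4.83, but 8 and 7 of them were at least 2-fold higher, as Cpr92F (2.34 and 2.68) was. Osi6 (-4.70 and -4.88) and ImpL1 (-3.69 and -4.05) were among the lowest. The nucleolus list was at -0.70 and -1.33, with 6 and 11 of 15 genes at least 2-fold lower and mod at -1.71 and -2.31. Muscle genes had medians of 0.27 and 0.67. Blood cell genes went both ways at 88 h, with the prophenoloxidases PPO2 (3.20) and PPO1 (2.81) higher and the collagen IV genes vkg (-1.35) and Col4a1 (-1.18) lower. At 76 h 191 genes were at least 2-fold higher and 259 lower, and at 88 h 297 and 390, or 139 and 137 at 3-fold.

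At 100 h the salivary glue and late gland genes were all higher, and respiratory chain genes were lower. Eig71Ee was at 7.17 and Sgs1, a glue protein gene, at 4.18, and all 6 genes of the list were at least 2-fold higher (median 2.46). Of the 48 genes matched for the respiratory chain list, related genes such as COX4L included, 25 were at least 2-fold lower and none higher. The list median was -1.04, against -0.09 at 88 h. ATPsynC (-1.97) and ATPsynG (-1.72) were the lowest. Most arrays of 100 h came from a lot that no other age used, so age and lot are not fully separate at this step. Nucleolus genes were at -1.50, with Nop56 at -2.90, and ribosomal protein genes at -0.58. Cuticle genes were at -1.05, with 34 of 68 at least 2-fold lower, TwdlD at -6.77 and TwdlF at -6.70, yet Cpr78E was at 5.33 and Cpr49Ac at 3.56. Osi6 was at -6.81 and CG14147 at -8.59. Immune genes were at 0.88, with 7 of 15 at least 2-fold higher and Drs at 3.13. In the insulin and TOR list (0.46), scyl was at 2.45 and ImpL2, an insulin binding protein gene, at 1.95. Lsp2 was at 8.26, CG42500 at 7.80, Fbp2 at 7.51, CG30029 at 7.16 and Obp99b at 6.94. At this age 457 genes were at least 2-fold higher and 623 lower.

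**Figure D4:**
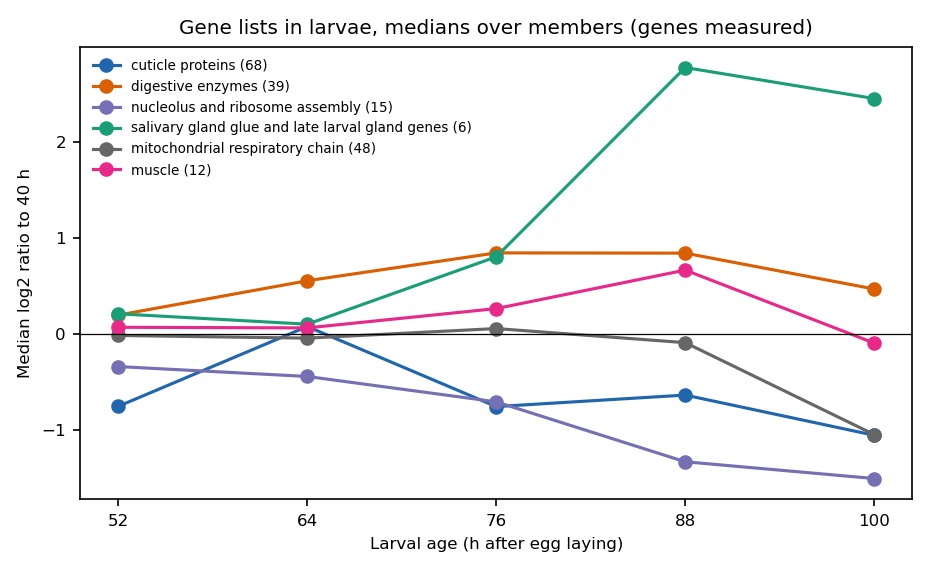
Lines join the median log2 ratio to 40 h larvae of 6 gene lists (y axis) at each larval age in hours after egg laying (x axis), with 1 merged value per gene and no error bars. The cuticle list was at -0.75, 0.08 and -0.75 at 52, 64 and 76 h, and the respiratory chain list lay at -1.04 at 100 h.

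With age, 133 genes had a higher ratio at each later age and ended at least 2-fold higher, and 213 had a lower ratio at each later age and ended at least 2-fold lower. Rising genes included mag (1.10 at 52 h to 5.57 at 100 h), Amy-p (0.77 to 3.71), Drs (0.56 to 3.13), PPO2 (0.49 to 3.55) and the cathepsin gene cathD (0.29 to 3.28). Falling genes included the nucleolar genes Nop56 (-0.27 to -2.90), mod (-0.68 to -2.66) and NHP2 (-0.38 to -2.70). These examples were chosen after their values were seen. The ages share 1 control age. A set of 14 genes, among them Lsp2, Fbp2, Obp99b, Jig and mag, were at least 2-fold higher at all 5 ages, and 7 were lower at all, among them TwdlC, TwdlD, Muc91C and CG14421.

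The medians of several fixed lists stayed near the control, over members that went both ways. The germline and early embryo list lay between -0.17 and 0.10 in all 12 groups, and the ecdysone list between -0.05 and 0.20. Autophagy genes lay between -0.09 and 0.30, and accessory gland and testis genes between -0.13 and 0.24. Single members were further away at 100 h, as the testis gene dj (2.24), Atg9 (1.73) and ImpL1 of the ecdysone list (-4.35) were, with 4 of 16, 3 of 10 and 3 of 19 members of these lists at least 2-fold higher. The 3 measured heat shock genes were too few for random lists. At 100 h l(2)efl, a small heat shock protein gene, was at 2.68, Hsp68 at 1.56 and the mitochondrial chaperone gene Hsc70-5 at -1.81. Fbp2, the other larval serum list member beside Lsp2, lay at -0.13 in females starved for 24 h and on sugar for 48 h. Of the 312 list medians in the 12 groups 171 lay outside the middle 95% of random lists, where 15.6 would by chance, and of the 234 for differences between groups 116 did, where 11.7 would. Genes of a list are not independent, so these figures describe the lists and test nothing.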

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

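All tests of explanations in this part were chosen after the result was seen. Genes were picked out where the same treatment gave a ratio at least 2-fold higher in 1 group and at least 2-fold lower in another that differed in sex, or in time and in part of its array lots. The gene nes was at 2.18 in females starved for 24 h and at -1.39 in males starved for 24 h. CG13558 was at 1 in females on sugar at 24 h and at -1 at 48 h. Atg12 was at 1.14 in males on sugar at 24 h and at -1.31 at 48 h. Each is 1 merged value per group, and none of these differences was tested.

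Muscle, eye and nervous system lists were higher in females on both diets, which a smaller share of ovary RNA could bring about by raising all other tissues alike, blood cells with muscle. At 24 h the gap between the muscle and blood cell medians exceeded the sum of their SDs in starvation (0.539 against 0.382) and on sugar (0.508 against 0.441). At 48 h the gap was wider but lay within that sum (0.709 against 0.904 and 0.798 against 1.13). The SDs are spreads over the genes of a list and not errors of its median. The muscle list thus lay above the blood cell list at both times, but this comparison cannot decide whether a smaller share of ovary RNA was the cause. The germline list of the ovary, at -0.12, -0.12, -0.01 and -0.17 in females starved for 24 and 48 h and on sugar for 24 and 48 h, decides nothing, since columns centred near 0 would hide a fall shared by many genes. The array lots do not explain it, since males on sugar at 48 h, on the same lots, had a muscle median of -0.0693. A change in the tissues themselves stays possible and was not tested.

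On sugar, the ratio of the purine and folate list to yeast was lower in males than in females. Each sex was set against its own yeast-fed control, so expression levels were not compared between the sexes. Muscle genes differed between the sexes by nearly as much, with a gap of 0.0904 between the lists at 48 h, so an offset shared with muscle genes may play a part. In starvation the lists lay apart by -0.554, past the SD of the purine and folate list (0.349), against what such an offset predicts. This gap lay within the sum of the SDs of both lists (0.575). Both limits are spreads over genes and not errors of a median, so they cannot decide, and the explanation stays open. A difference in metabolism between the sexes stays open and was not tested.

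The cuticle list was lower at 52 and 76 h but not at 64 h. The spread over genes was smaller at 64 h (SD 0.312, against 0.354 at 52 h and 0.529 at 76 h). The list median at 64 h was 0.108 of the mean size at both neighbouring ages for the cuticle list. For 11 other lists this share had a median of 0.759 (SD 0.398). Those lists ranged from 0.206 (salivary gland) to 1.48 (ribosomal proteins), taken without sign. This argues against a compression shared by all lists as the whole cause, but does not exclude a part of it. A cycle of cuticle genes with the moults, with the 40 h control near the phase of 64 h, would give the same course in the Osi genes. The Osi genes were picked after the results were seen, with Osi2 and Osi6 already among the lowest, so they are no independent check. Their median was -0.0197 at 64 h, against -0.48 at 52 h and -0.27 at 76 h, which is consistent with such a cycle. The 40 h control was not set against an earlier age, so these data do not give its phase.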

How the results depend on the processing

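With columns centred, with genes measured in every group, with each clone by itself and with the first clone of a gene, all 12 counts of genes past 2-fold stayed within 1.5 times. Centring and complete genes also kept all 9 counts of differences within that range. Centring shifted the share of genes on the higher side most in starved against sugar-fed females at 48 h, by -5.14 points to 79.7%. The number of lists outside random lists, 171, was 151 with list means, 171 with centring, 170 with complete genes, 163 without the most extreme members and 171 with names from the files alone. Only the 63 list medians outside random lists and at least 0.4 from 0 were run, so a reversal was hardly possible, and none was seen, and smaller medians were not run. Leaving out the most extreme member in each direction keeps a median by construction. With the mean, 8 moved, and with complete genes 1 moved. Among the 8 highest and 8 lowest genes of the groups, 12 values came from genes with more than 1 clone. Of these 12, whether their clones agreed or not, 8 moved with the first clone and none reversed. The cause of these moves was not tested.

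By construction, counts followed the threshold. At 1.5-fold they were 392 and 773 in starved females, 173 in starved males, 461 and 868 in females on sugar, 249 and 391 in males on sugar, and 491, 564, 1243, 1566 and 2363 in larvae from 52 to 100 h. At 3-fold they were 41, 50, 18, 53, 82, 35, 84, 88, 27, 173, 276 and 447 in the same order. For differences, 1.5-fold gave 363, 367 and 1456 between the sexes (starved, then sugar at 24 and 48 h), 85, 419 and 158 between starvation and sugar (females at 24 and 48 h, males), and 552, 389 and 186 between 48 and 24 h (starved females, females and males on sugar). At 3-fold these were 31, 38, 75, 1, 14, 9, 11, 9 and 8. The balance between higher and lower genes turned in 9 cases. At 3-fold it was 14 to 36 and 29 to 53 in starved and sugar-fed females at 48 h, 139 to 137 in larvae of 88 h, 31 to 44 between the sexes on sugar at 48 h, 0 to 1 between starvation and sugar in females at 24 h, and 4 to 7 between 48 and 24 h in starved females. At 1.5-fold it was 216 to 147 and 211 to 156 between the sexes at 24 h, starved and on sugar, and 87 to 71 between starvation and sugar in males. The cause of these turns was not tested. With the sign turned, the direction check gave -8.52 and -8.26 in larvae of 88 and 100 h and -0.0358, -0.78 and 0.0159 in starved females at 24 and 48 h and starved males, also by construction.

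The larval trend counts of 133 higher and 213 lower were 266 and 354 without 52 h, 255 and 365 without 64 h, and 354 and 421 with rank order alone, in part because fewer steps or no limit on size were asked for; otherwise the cause was not tested. Without 76, 88 or 100 h they stayed within 1.5 times.

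No paired analysis was possible because all columns of a group hold the same merged values. For the same reason the model with a replicate block, the dye term, the lot block, fits without each replicate, each group fitted alone and the sign-flip test were not run. Keeping genes with a value in all columns of the group moves nothing by construction. Signal over background is not part of the values used, so the background filter was not run and weak spots were not set apart.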

Other observations

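Maltases, enzymes that split sugars in the gut, were lower in males on sugar, with a median over 8 genes of -1.13 at 24 h (7 at least 2-fold lower) and -1.69 at 48 h (all 8). In females on sugar it was -0.95 and -0.60, in starved females -0.54 and 0.04, and in starved males -0.64. The Jonah serine proteases (13 genes) had a median of -0.96 and -2.34 in males on sugar at 24 and 48 h, -1.49 in starved males, -0.71 and -0.80 in females on sugar and -0.44 and -0.41 in starved females, and of 0.79, 1.08, 1.18 and 0.92 in larvae from 64 to 100 h. These families were chosen after their values were seen.

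Cyp4g1 and FASN2, both tied to oenocytes and hydrocarbon synthesis, were among the 14 genes at least 2-fold higher in all 4 female comparisons, where 46 were lower in all. In the 3 male comparisons 0 were higher and 31 lower in all. A gene without a value in a comparison could not be counted. Of the 10 genes at least 2-fold higher in males on sugar at 24 h, 9 had a value at 48 h. The 0 may thus rest in part on a missing value. Across all 7 adult comparisons 6 genes were lower, Lsp2, CG11538, Jon25Bi, CG18180, CG10621 and CG3699, and 0 were higher. In these counts Lsp2 and CG11538 are taken singly, though the pair is uncertain as separate genes. The Twdl cuticle family (15 genes) had medians of -2.68, -0.35, -3.28, -3.49 and -3.95 from 52 to 100 h.

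Some genes passed 4-fold in a single adult comparison and stayed under 2-fold in the other 6. Among them were pwn (-2.64), DnaJ-H (-2.20) and CG15879 (-3.36) in starved males, and LManV (-2.86) in males on sugar at 48 h. In females they included Cyp4e3 (2.42) after 48 h of starvation, and CG7798 (2.74) and CG14668 (-2.50) after 24 and 48 h of sugar. Each of these examples rests on 1 clone. Lsp2 and CG11538 differed by 0.13 to 0.84 across the 12 groups. The odorant receptor family (42 genes in adults) had medians from -0.17 to -0.04 in the adult groups. Clones without a gene name passed 2-fold in 156 of 1942 cases at 100 h and in 4 of 1939 in starved males.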
